A study of Mus musculus with 42 samples.

How the data were processed

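RNA came from cells of mice aged 8 to 12 weeks, was extracted with TRIzol and an RNeasy kit, made into libraries with the TruSeq RNA kit v2 and read single-end, as 50 or 36 bases, on a HiSeq 2000 or NextSeq 550, per the labels. The labels do not say which library was read on which instrument, and no batch or date is given in the sources used here.

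Reads were trimmed with Trim Galore 0.4.1, aligned with HISAT2 2.0.1 and counted with featureCounts 1.4.6, per the submitters' processing notes, which name the builds GRCm38 and mm10. In the KO set the FPKM values were computed by the authors per kilobase of gene and scaled to the number of fragments, and are used here as deposited. The TPM values of the same files were scaled by the authors so that each library sums to the same total, per the headers and sums. The coverage values were computed by the authors as mean read depth per base of each gene, per the file headers. Aligned sequence per library was taken as the constant ratio of coverage to FPKM. In the Sle3 set the RPKM values were computed by the authors per kilobase of gene and scaled to the number of mapped reads, as deposited. No source used here names the program that made either kind of table, and none of the files holds read counts.

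The branch of the plan for normalized values therefore applied. In the KO set 54752 gene IDs were read, and in the Sle3 set the 29233 names found in all 10 files entered the additive fit, while single pairs used all names of their cell type. Values were put on the scale log2(value + 1), so a fold change of a gene with low values is understated, and log2 fold changes are differences of mean log2 values. Genes at 1 or more in at least 2 libraries were tested (at least 4 in the Sle3k fit). One cell-means model per cell type over its 6 groups was fitted with limma 3.58.1 (lmFit, eBayes with trend and robust options), and p-values were adjusted by the Benjamini-Hochberg method at an FDR of 0.05. In BMDM, and for Sle3k against B6, genotype or strain was fitted with the 4 conditions as blocks, which leaves 3 residual degrees of freedom and cannot separate genotype from anything else shared by all libraries of 1 genotype.

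In total 30 gene lists were written from general knowledge, without values. They covered proinflammatory cytokines, chemokines, T effector cytokines, early TCR activation, naive T cell quiescence, T helper lineage, regulatory T cells, interferon-stimulated genes, MHC class II, dendritic maturation, the TLR pathway, NF-kB feedback, the KLF and SP family, proliferation, cholesterol synthesis, glycolysis, alternative activation, chromatin modifiers, sex-linked genes, and markers of B cells, CD8 T cells, NK cells, myeloid cells, neutrophils, erythroid cells, mast cells, T cells, macrophages, dendritic cells and stroma. They were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, and p-values were adjusted over the lists of a contrast. Members were counted over all genes tested and adjusted over the list alone. Some lists share members, and resident or activated T cells express part of the NK, dendritic and myeloid markers.

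Pairs of single libraries have no test. Genes at 5 or more in 1 of the pair were counted when they differed by at least 2-fold, and a list's median log2 ratio was ranked among the medians of 10000 random lists matched on level. This rank ignores spread between samples. Planned exact intervals could not be computed without counts.

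The main tests, the lists, most other settings and the rule for naming genes were fixed before the data were examined, while tests and settings chosen later are named where they are given. By that rule Klf13 came first, then in each KO comparison the 5 largest rises and falls among called genes with a mean of 5 or more in 1 group and the same direction in every replicate. Predicted gene models and pseudogenes were excluded from naming, and the script also left out microRNA, small nucleolar RNA and clone names, which the rule did not list. Genes that meet all of this are called eligible, and the limit on the mean did not apply in the additive fits. Up to 4 called members per list followed, or the 2 with the highest mean, then the 3 largest changes each way of stimulus and interaction terms, and a panel of cytokines. The text names part of the genes so chosen. Values are given as mean ± SD over the 2 libraries of a group, and a group with no value above 0 is said to be listed at 0.

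The share of called genes near Klf13 was compared with that of all tested genes, in windows of 5, 20 and 40 Mb, by Fisher's exact test, leaving out Klf13 itself. Directions of the Sle3k and KO effects were compared with 95% exact binomial intervals. Other splits of the libraries were refitted, in T cells and BMDC 100 splits balanced within conditions, and in BMDM and Sle3k the 32 splits into equal arms that could be fitted. Splits within the pairs of a condition, and splits that keep BMDC of a genotype and replicate number together, were added later. Before use, the scripts were run on simulated values with 200 genes changed by known amounts. Of 20 simulated unchanged lists 0 were called, which does not cover correlated genes. Software was R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.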

Results

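Transcript levels were measured in 42 mouse RNA-seq libraries of 30 groups and 3 cell types: CD4 T cells, bone marrow-derived dendritic cells (BMDC) and bone marrow-derived macrophages (BMDM). The Klf13 knockout (KO) set held 32 libraries of KO and wild-type (WT) cells. Its naive CD4 T cells from spleen were taken at 0 h, or after 6 h or 18 h with anti-CD3 and anti-CD28 (12 libraries, 2 per group). Its BMDC were unstimulated or kept for 6 h with 10 ng/ml LPS, a TLR4 ligand, or with 1 µg/ml R848, a TLR7 ligand (12 libraries, 2 per group). Its BMDM were unstimulated or kept for 6 h with LPS, with R848 or with 1 µM of the TLR9 ligand ODN1826 (8 libraries, 1 per group). The Sle3 set held 10 libraries with 1 per group, and compared the lupus-prone congenic strain written Sle3k here with B6. It also held a pair of sub-congenic T cell libraries at 0 h. Aligned sequence was 0.943 to 2.21 Gb per T cell library, 1.37 to 1.87 Gb per BMDC library and 0.817 to 1.65 Gb per BMDM library of the KO set. Genes at 1 FPKM or more numbered 14906 to 15802, 13043 to 13964 and 13211 to 14799 in the same order. In the Sle3 set, 11269 to 12213 genes reached 1 RPKM in T cells and 9926 to 10312 in BMDC. Nothing in the labels says that replicates came from separate animals or cultures, so every p-value below measures only the spread between these samples.

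Klf13 encodes a zinc-finger transcription factor of the Krüppel-like family and lies on chromosome 7 (GRCm38 63886351 to 63938915). Its transcript was still listed in all KO libraries. In T cells it stood at 35.5 and 34.0 FPKM in WT against 20.3 and 20.4 in KO at 0 h, at 46.1 and 58.2 against 18.0 and 14.4 at 6 h, and at 44.4 and 43.1 against 8.9 and 14.8 at 18 h. Each of these differences passed limma (log2 fold change -0.74, -1.63 and -1.83, adjusted p = 0.044, 0.0018 and 0.0017). In BMDC it stood at 24.4 and 22.2 in WT against 18.8 and 21.3 in KO without stimulus, at 13.5 and 14.2 against 7.4 and 7.0 with LPS, and at 13.6 and 14.0 against 20.2 and 12.2 with R848. Only the LPS difference passed limma (log2 fold change -0.85, adjusted p = 0.03, against 0.57 unstimulated and 0.62 with R848), and the library labelled KO R848 replicate 1 lay above both WT libraries. Leaving out any 1 library ended the limma call at 0 h (adjusted p = 0.159 to 0.188) and the call with LPS (0.103 to 0.149). In BMDM the WT and KO values were 17.5 and 10.5 unstimulated, 6.3 and 1.3 with LPS, 9.1 and 1.8 with R848, and 8.3 and 2.2 with ODN1826. In the Sle3 set B6 and Sle3k T cells had 47.9 and 45.5 RPKM at 6 h and 16.6 and 21.6 at 18 h. B6 and Sle3k BMDC had 13.1 and 12.3 unstimulated and 10.3 and 10.9 with R848.

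**Figure D1:**
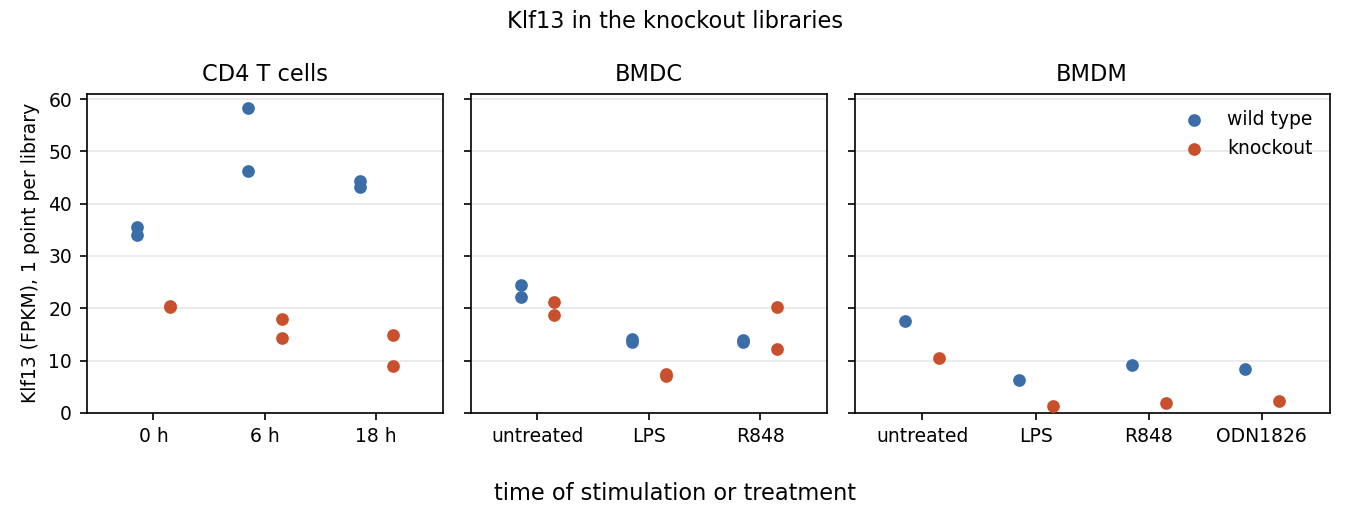
Klf13 in each of the 32 libraries of the KO set, in T cells, BMDC and BMDM, with FPKM on the vertical axis, time or treatment on the horizontal axis and 1 point per library. The lowest KO value was 1.3 FPKM in BMDM with LPS.

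In naive CD4 T cells at 0 h, cell-cycle genes were lower in KO and markers of several other cell types differed as well. Of 24 proliferation genes 20 fell and none rose (24 fell adjusted over the list alone), with a list median of -0.70 (camera adjusted p = 2.9e-16, but adjusted p = 0.062 with an estimated correlation). Birc5, which is needed for chromosome segregation, fell from 107 ± 0.199 to 50.5 ± 0.085 FPKM (mean ± SD, n = 2, log2 fold change -1.06). The mitotic cyclin gene Ccnb1 fell from 41.1 ± 0.972 to 18.7 ± 3.86 (-1.11), and Rrm2, which makes deoxynucleotides for DNA synthesis, from 143 ± 0.446 to 71.9 ± 1.21 (-0.98). Erythroid genes fell alongside, 9 of 10 (10 adjusted over the list alone, median -1.01, camera adjusted p = 7.5e-08, but adjusted p = 0.10 with an estimated correlation). The red-cell membrane gene Slc4a1 fell from 199 ± 0.997 to 70.8 ± 1.64 (-1.48). Neutrophil genes went the other way, 9 of 10 rising (9 adjusted over the list alone, median 2.35, camera adjusted p = 4.2e-11, but adjusted p = 0.062 with an estimated correlation). The granule enzyme gene Mpo rose from 7.96 ± 0.508 to 67.6 ± 5.77 (2.94), and the calprotectin genes S100a8 and S100a9 rose from 0.442 ± 0.01 to 8.31 ± 0.504 (2.69) and from 1.37 ± 0.099 to 14.7 ± 0.663 (2.73). Macrophage genes rose in 7 of 11 (10 adjusted over the list alone, median 0.66, adjusted p = 1.4e-06, but adjusted p = 0.091 with an estimated correlation), among them Csf1r from 20.8 ± 0.132 to 47.3 ± 1.18 (1.15) and Apoe from 63.2 ± 0.721 to 147 ± 21.4. General myeloid genes rose in 5 of 12 (6 adjusted over the list alone, median 0.56, adjusted p = 2.7e-05, but adjusted p = 0.15 with an estimated correlation). The limma calls of Ccnb1 and Apoe ended without either WT replicate or without KO replicate 1 (adjusted p = 0.0508 to 0.0917).

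Several genes of T cell identity, quiescence and early signalling were higher in KO T cells at 0 h. Of 10 T cell markers 6 rose (8 adjusted over the list alone, median 0.39, camera adjusted p = 2.7e-05, but adjusted p = 0.068 with an estimated correlation). The receptor-signalling genes Lck and Lat rose from 244 ± 2.17 to 350 ± 3.92 FPKM (mean ± SD, n = 2, log2 fold change 0.51) and from 259 ± 2.15 to 376 ± 1.13 (0.53). Of 18 genes of naive quiescence 12 rose (14 adjusted over the list alone, median 0.52, adjusted p = 7.5e-08, but adjusted p = 0.21 with an estimated correlation). Lef1, a transcription factor of naive T cells, rose from 55.5 ± 2.54 to 94.3 ± 5.91 (0.75), and Tsc22d3, a glucocorticoid-induced regulator, from 13.8 ± 0.195 to 112 ± 39.3 (2.88). Early T cell receptor (TCR) activation genes rose in 11 of 22 and fell in 1 (14 and 1 adjusted over the list alone, median 0.43, adjusted p = 1.4e-06, but adjusted p = 0.19 with an estimated correlation). The immediate early gene Nr4a1 rose from 21.9 ± 0.398 to 47 ± 0.483 (1.07), while the transferrin receptor gene Tfrc fell from 191 ± 19.4 to 104 ± 0.743 (-0.86). Regulatory T cell genes rose in 6 of 12 (9 adjusted over the list alone, median 0.50, adjusted p = 3.8e-06, but adjusted p = 0.063 with an estimated correlation). The lineage factor Foxp3 went from 26.5 ± 0.509 to 43.6 ± 0.215 (0.70) and Gpr83 from 7.42 ± 0.07 to 19.4 ± 0.439 (1.27). Interferon-stimulated genes rose in 17 of 30 and fell in 1 (21 and 1 adjusted over the list alone, median 0.51, adjusted p = 4.5e-07, but adjusted p = 0.063 with an estimated correlation). Among them Ifi44 rose from 3.97 ± 0.308 to 9.8 ± 0.158 (1.12). Among genes eligible for naming the largest rise beside Mpo and Tsc22d3 was in Ctrb1, a pancreatic protease precursor gene (3.38, 0.234 ± 0.017 to 11.8 ± 0.532). The largest falls were in the receptor kinase gene Mst1r (-4.10, 18.5 ± 7.37 to 0.098 ± 0.138), Htatip2 (-4.09, 19.7 ± 0.117 to 0.212 ± 0.004), Ighg3 (-3.64) and Igkv12-89 (-2.55). Ighv3-7 stood at 7.98 ± 1.01 in WT and was listed at 0 in KO. Immunoglobulin genes are close paralogs, so their single values are uncertain. Leaving out any 1 of the 4 libraries ended the limma calls of Lck, Lef1, Tsc22d3, Tfrc and Foxp3 (adjusted p = 0.0502 and above, up to 0.114 apart from Tsc22d3), and leaving out WT replicate 2 that of Lat (0.0539).

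Innate-response lists were also tested in T cells at 0 h. TLR pathway genes rose in 8 of 21, NF-kB feedback genes rose in 5 of 17 and fell in 1, and MHC class II genes rose in 2 of 10 (9, 8 and 1, and 7 adjusted over the list alone). Camera called these lists at adjusted p = 0.00016, 0.00051 and 0.0014, but adjusted p = 0.10, 0.27 and 0.15 with an estimated correlation. Dendritic maturation genes rose in 7 of 19, T helper lineage genes in 5 of 19 and alternative activation genes in 3 of 11 (8, 6 and 3 adjusted over the list alone). These lists passed at adjusted p = 0.0016, 0.0028 and 0.0072, but adjusted p = 0.063, 0.24 and 0.19 with an estimated correlation. The NF-kB inhibitor genes Tnfaip3 and Nfkbia rose from 22.3 ± 1.14 to 42.4 ± 0.685 FPKM (mean ± SD, n = 2, log2 fold change 0.90) and from 80 ± 1.41 to 136 ± 2.63 (0.76). Of 12 proinflammatory cytokines 3 rose, Il12a (0.86), Osm (0.56) and Ebi3 (0.38). No chemokine of 14 passed, nor any of 3 stroma markers or 4 sex-linked genes. Other lists without a call had few changed members, namely 2 of 20 effector cytokines, 5 of 15 KLF and SP family genes including Klf1 (-0.77) and Klf2 (0.71), 2 of 20 cholesterol synthesis genes, 2 of 17 glycolysis gene models, and 1 of 16 chromatin modifiers (Kdm6b 0.90). Among markers 4 of 11 B cell, 1 of 7 NK, 2 of 10 mast cell and 5 of 9 dendritic genes passed. The CD8 T cell list had a single tested member, Cd8b1, at 4.18 FPKM in KO and 3.28 in WT (limma adjusted p = 0.31). In total limma called 2656 of 17060 genes at an FDR of 0.05, 1399 higher and 1257 lower in KO. This count fell when any 1 library was left out, to 659 and 641 without WT replicate 1 or 2 and to 899 and 791 without KO replicate 1 or 2. It was 1738 (1184 higher, 554 lower) on TPM, 5741 when the 0 h libraries were fitted alone, 6912 with a variance weight per group and 5507 without the 6 h libraries. The limma calls of Tnfaip3, Osm, Ebi3 and Klf2 ended without any 1 library (adjusted p = 0.0765 to 0.243), that of Kdm6b without WT or KO replicate 2 (0.0541), and that of Il12a in each case but KO replicate 2 (up to 0.118).

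**Figure D2:**
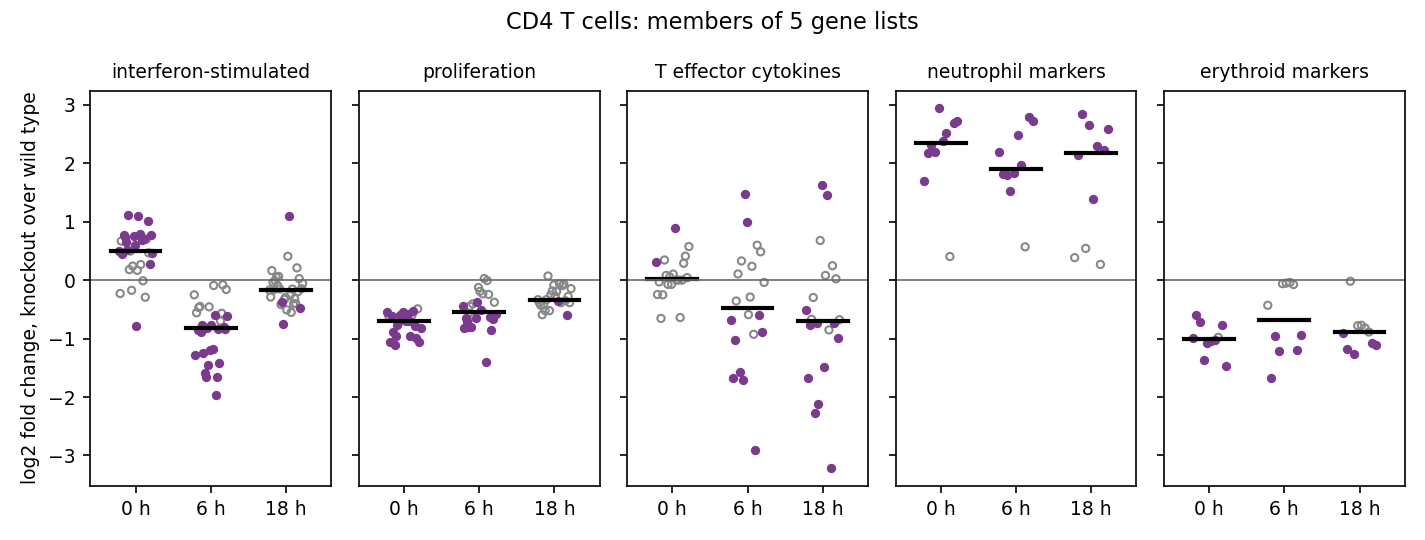
Log2 fold change (KO over WT, vertical axis) of the members of 5 gene lists in T cells at 0 h, 6 h and 18 h, 1 point per gene, filled where limma called the gene, with a bar at the median. The median of the neutrophil list was 2.35, 1.90 and 2.18.

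After 6 h of activation interferon-stimulated genes were lower in KO T cells, while effector cytokines differed in both directions. Of 30 interferon-stimulated genes 20 fell and none rose (24 adjusted over the list alone, median -0.82, camera adjusted p = 6.9e-17, and adjusted p = 0.026 with an estimated correlation). The 2-5A synthetase genes Oas2 and Oas3, sensors of viral RNA, fell from 18.8 ± 0.433 to 4.05 ± 0.316 FPKM (mean ± SD, n = 2, log2 fold change -1.97) and from 17.3 ± 1.89 to 4.83 ± 0.987 (-1.66). Ifit1 fell from 57.4 ± 7.82 to 17.8 ± 4.43 (-1.65), and Ifih1, which encodes the RNA sensor MDA5, from 42.2 ± 2.56 to 13.4 ± 1.15 (-1.58). Of 20 effector cytokines 8 fell and 2 rose (8 and 3 adjusted over the list alone), although the list did not pass limma camera (median -0.47, adjusted p = 0.11). Il4 went from 118 ± 56.6 to 16.8 ± 13.7 (-2.91), Ifng from 39.4 ± 15.7 to 12.7 ± 6.03 (-1.57) and Csf2 from 21.7 ± 4.41 to 6.43 ± 3.21 (-1.67), whereas Il17a rose from 0.885 ± 0.023 to 4.22 ± 0.384 (1.47). Il2 did not pass (20.5 ± 6.83 in WT, 13.7 ± 6.48 in KO, limma adjusted p = 0.23). Tbx21, a lineage factor of Th1 cells, fell from 16.8 ± 1.04 to 7.65 ± 2.39 (-1.07). The T helper list had 3 up and 4 down of 19 without a list call. Proinflammatory cytokines fell in 3 of 12, Tnf among them (73 ± 1.29 to 40.2 ± 12.5, -0.88), and chemokines fell in 5 of 14 and rose in 2, with the macrophage-attracting Ccl3 going from 74.1 ± 9.05 to 21.3 ± 13.2 (-1.89) and Cxcl10 from 48.4 ± 3.71 to 21.5 ± 6.44 (-1.16). The limma call of Ifng ended without WT replicate 1 (adjusted p = 0.0630), that of Tnf without WT replicate 2 (0.0593) and that of Cxcl10 without WT replicate 2 or KO replicate 1 (up to 0.0902), while Il2 passed without KO replicate 2 (0.0290).

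Several other lists in T cells at 6 h had medians signed as at 0 h, but early TCR genes did not. Neutrophil genes rose in 9 of 10 (9 adjusted over the list alone, median 1.90, limma camera adjusted p = 3.5e-11, and adjusted p = 0.039 with an estimated correlation), S100a8 from 0.83 ± 0.189 to 11.9 ± 3.99 FPKM (mean ± SD, n = 2, log2 fold change 2.79). Proliferation genes fell in 14 of 24 (16 adjusted over the list alone, median -0.55, adjusted p = 2.4e-10, but adjusted p = 0.13 with an estimated correlation), Mki67 from 23.4 ± 1.82 to 8.25 ± 0.71 (-1.40). Erythroid genes fell in 5 of 10 (5 adjusted over the list alone, median -0.68, adjusted p = 0.00014, but adjusted p = 0.36 with an estimated correlation), the carbonic anhydrase gene Car1 from 147 ± 5.2 to 46.2 ± 11.4 (-1.67). Quiescence genes rose in 7 of 18 (11 adjusted over the list alone, median 0.58, adjusted p = 4.8e-07, but adjusted p = 0.43 with an estimated correlation). The homing receptor gene Ccr7 went from 134 ± 15.4 to 257 ± 39.5 (0.93) and Tcf7 from 141 ± 12.4 to 259 ± 38.9 (0.87). T cell, myeloid and macrophage markers rose in 5 of 10, 6 of 12 and 2 of 11 (7, 7 and 6 adjusted over the list alone, adjusted p = 0.00014, 0.0002 and 0.001, but adjusted p = 0.13, 0.36 and 0.36 with an estimated correlation). Early TCR genes were divided, 3 up and 5 down of 22 (4 and 10 adjusted over the list alone). Irf4, a factor that scales with TCR signal, fell from 132 ± 17.8 to 64.1 ± 5.97 (-1.03), and the inhibitory receptor gene Pdcd1 rose from 34.2 ± 0.052 to 70.4 ± 6.1 (1.01). At this time limma called 2035 genes, 885 higher and 1150 lower. Among genes eligible for naming the largest rise was again Ctrb1 (3.07), and the largest falls were Iglj2 (-7.70), Htatip2 (-3.94) and Igkv12-89 (-3.34). The count was 1066 without WT replicate 2 and 3230 without KO replicate 1, 167 with the 6 h libraries fitted alone and 388 with a variance weight per group. In simulated values of this comparison 193 unchanged genes were called beside the true ones. The call of Iglj2 ended without any 1 library (limma adjusted p = 0.0742 to 0.107).

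At 18 h more effector cytokines were lower than higher in KO T cells. Of 20 effector cytokines 10 fell and 2 rose (12 and 3 adjusted over the list alone, median -0.70, camera adjusted p = 9.8e-05, but adjusted p = 0.54 with an estimated correlation). Il4 fell from 65.8 ± 2.9 to 6.26 ± 1.02 FPKM (mean ± SD, n = 2, log2 fold change -3.21), Ifng from 96.7 ± 2.68 to 19.4 ± 3.68 (-2.27), Il13 from 34.3 ± 3.96 to 7.19 ± 1.17 (-2.11) and the T cell growth factor Il2 from 30.4 ± 2.76 to 10.1 ± 0.62 (-1.49). Tnf fell from 70.3 ± 1.52 to 35.1 ± 2.44 (-0.98) and Il10 from 9.17 ± 0.108 to 5.17 ± 1.04 (-0.73), while Il17a did not pass limma (0.68, adjusted p = 0.1). Chemokine genes Ccl1 (-2.46) and Ccl3 (-2.00) and the cytotoxic granule gene Nkg7 (-3.07, 50 ± 2.54 to 5.07 ± 0.137) also fell. Neutrophil genes rose in 7 of 10 (7 adjusted over the list alone, median 2.18, adjusted p = 2.5e-13, and adjusted p = 0.046 with an estimated correlation). Mpo went from 6.38 ± 0.297 to 45.2 ± 1.16 (2.65) and the elastase gene Elane from 0.422 ± 0.149 to 9.17 ± 0.983 (2.84). Myeloid genes rose in 5 of 12 (6 adjusted over the list alone, adjusted p = 2.6e-08, but adjusted p = 0.17 with an estimated correlation). Erythroid genes fell in 5 of 10 (9 adjusted over the list alone, median -0.90, adjusted p = 1.1e-09, but adjusted p = 0.17 with an estimated correlation) and proliferation genes in 2 of 24 (10 adjusted over the list alone, median -0.33, adjusted p = 4.7e-08, but adjusted p = 0.17 with an estimated correlation). NK genes fell in 2 of 7 (2 adjusted over the list alone), Klrk1 (-1.35) and Gzma (-1.23), and interferon-stimulated genes fell in 3 of 30 and rose in 1 (3 and 1 adjusted over the list alone), at adjusted p = 0.0016 and 0.0063, but adjusted p = 0.33 and 0.33 with an estimated correlation. MHC class II and quiescence lists passed without a called member (adjusted p = 0.021 and 0.026, but adjusted p = 0.41 and 0.69 with an estimated correlation). Htatip2 stood at 14.6 ± 0.091 in WT and was listed at 0 in KO. By genotype limma called 738 genes, 352 higher and 386 lower. Leaving out 1 library gave 394 and 397 (WT replicate 1 or 2) and 339 and 373 (KO replicate 1 or 2), while variance weights gave 1416 and leaving out the 6 h libraries 1567. Calls of Il4, Il2, Tnf, Il10, Ccl3 and Gzma ended without any 1 of the 4 libraries (limma adjusted p = 0.0512 to 0.271), that of Ifng without KO replicate 1 (0.0518) and that of Il13 without WT replicate 2 or KO replicate 1 (up to 0.0739), while Il17a passed without KO replicate 2 (0.00863).

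Averaged over the 3 times, limma called 3460 genes in T cells by genotype, 1714 higher and 1746 lower in KO, and 5383 when the 6 h libraries were left out. Proliferation genes fell in 21 of 24 (23 adjusted over the list alone, median -0.51, camera adjusted p = 2.0e-15, but adjusted p = 0.070 with an estimated correlation) and erythroid genes in all 10 (10 adjusted over the list alone, adjusted p = 6.7e-09, but adjusted p = 0.13 with an estimated correlation). Neutrophil genes rose in 9 of 10 (9 adjusted over the list alone, median 2.17, adjusted p = 6.4e-13, but adjusted p = 0.053 with an estimated correlation) and quiescence genes in 13 of 18 (13 adjusted over the list alone, adjusted p = 1.1e-08, but adjusted p = 0.26 with an estimated correlation). Interferon-stimulated genes fell in 12 of 30 and rose in 1 (13 and 1 adjusted over the list alone, median -0.13, adjusted p = 0.0016, but adjusted p = 0.19 with an estimated correlation). Effector cytokines fell in 10 of 20 and rose in 4 (10 and 4 adjusted over the list alone, limma camera adjusted p = 0.061), with Il4 (-2.25), Ifng (-1.17) and Il2 (-0.66) down and Il17a (0.73) up. Among genes eligible for naming, so without small RNA genes and predicted models, the largest average changes included Ctrb1 (3.24), S100a9 (2.68), Htatip2 (-4.00), Igkv12-89 (-2.83) and Mst1r (-2.68). The call of Il2 ended without 1 library in 8 of 12 cases, among them each 0 h library, WT 6 h and 18 h replicate 1 and both KO 18 h libraries (limma adjusted p = 0.0502 to 0.0682).

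**Figure D3:**
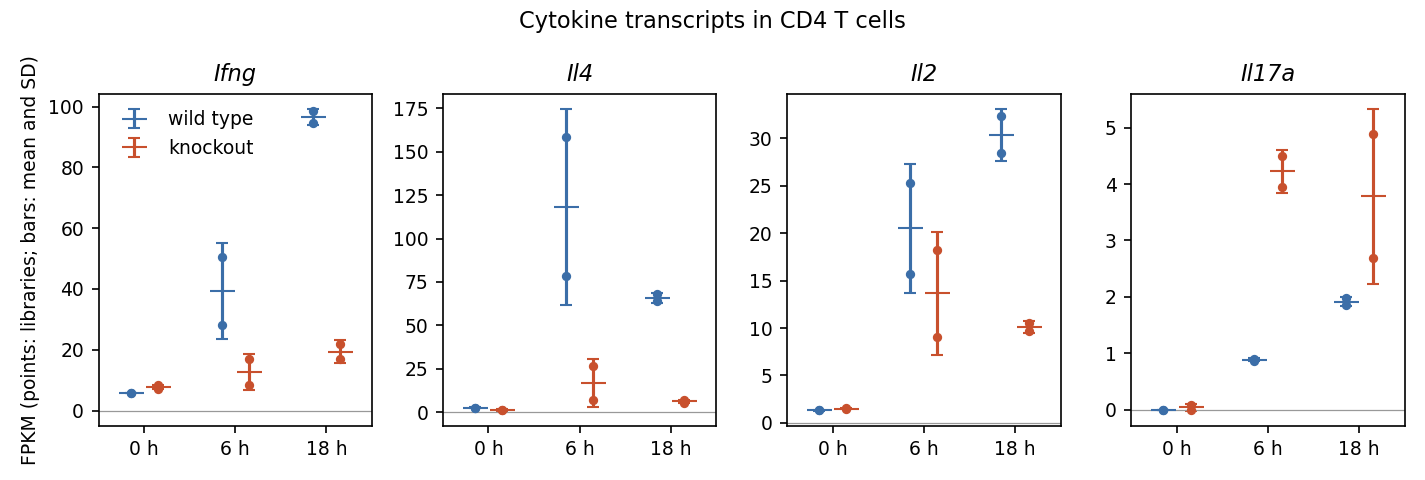
Ifng, Il4, Il2 and Il17a in T cells of the KO set, with FPKM on the vertical axis and time on the horizontal axis, 1 point per library and bars for the mean and SD (n = 2). Ifng at 18 h averaged 96.7 FPKM in WT and 19.4 in KO.

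Activation itself changed WT T cells widely. At 6 h interferon-stimulated genes rose in 26 of 30 and fell in 2 (27 and 2 adjusted over the list alone, median 1.65, camera adjusted p = 1.0e-15, and adjusted p = 0.020 with an estimated correlation), led by the interferon-induced GTPase genes Gbp2 (log2 fold change 5.25) and Gbp5 (4.78). Among eligible genes Gbp2b (5.90), Gbp2 and Il4 rose most, and Abcg4 (-3.81) and the macrophage complement genes C1qc (-3.80) and C1qb (-3.71) fell most. Early TCR genes rose in 19 of 22 and fell in 2 (19 and 2 adjusted over the list alone, adjusted p = 2.6e-14, but adjusted p = 0.087 with an estimated correlation), and effector cytokines rose in 16 of 20 (16 adjusted over the list alone, adjusted p = 1.8e-09, but adjusted p = 0.23 with an estimated correlation). Proliferation genes fell in all 24 (24 adjusted over the list alone, median -1.91, adjusted p = 2.6e-14, and adjusted p = 0.044 with an estimated correlation). At 18 h effector cytokines rose in 16 of 20 (19 adjusted over the list alone, adjusted p = 5.7e-10, but adjusted p = 0.14 with an estimated correlation) and cholesterol synthesis genes in 18 of 20 (19 adjusted over the list alone, adjusted p = 5.3e-09, but adjusted p = 0.056 with an estimated correlation). Glycolysis models rose in 11 of 17 and fell in 2 (11 and 2 adjusted over the list alone, adjusted p = 0.00038, but adjusted p = 0.11 with an estimated correlation). Erythroid genes fell in all 10 at 18 h (10 adjusted over the list alone, median -2.46, adjusted p = 1.1e-07, but adjusted p = 0.10 with an estimated correlation) and proliferation genes in 22 of 24 (23 adjusted over the list alone, median -1.97, adjusted p = 6.2e-13, but adjusted p = 0.056 with an estimated correlation). Among eligible genes Ccl1 (7.07), Crabp2 (5.51) and Gbp2b (5.21) rose most at 18 h, and the heat-shock genes Hspa1b (-5.87) and Hspa1a (-5.74) and C1qa (-5.62) fell most. Klf13 did not pass limma in WT at 6 h (0.56, adjusted p = 0.055) or 18 h (0.32, adjusted p = 0.25). Altogether limma called 7569 genes at 6 h (2793 up, 4776 down, or 3793 and 3769 after median centring) and 7166 at 18 h (3327 up, 3839 down, or 4648 and 3019 on TPM).

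The change from 0 h differed between genotypes most clearly in the interferon genes. In the test of interaction at 6 h, 17 of 30 interferon-stimulated genes responded less in KO and none more (28 adjusted over the list alone, median -1.25, camera adjusted p = 1.6e-25, and adjusted p = 0.0083 with an estimated correlation). Ifi44 (-2.36), Oas3 (-2.34), Oas2 (-2.24) and Ifit1 (-2.15) led the list. Early TCR genes responded less in 8 of 22 (12 adjusted over the list alone, median -0.68, adjusted p = 1.0e-06, but adjusted p = 0.39 with an estimated correlation), with Lag3 (-1.32), the IL-2 receptor gene Il2ra (-1.28) and Nr4a1 (-1.11). Il17a responded more (1.42, limma adjusted p = 0.038), while Ifng (-1.92, adjusted p = 0.064) and Il4 (-2.27, adjusted p = 0.12) did not pass. Among eligible genes Dkkl1 (1.69), Ackr1 (1.42) and Khdrbs3 (1.37) had the largest positive terms and Rnf213 (-2.65) and Trim30c (-2.56) the largest negative terms beside Ifi44. At 18 h Ifng (-2.61) and Cd40lg (-0.82) responded less, and Il17f (1.71) and Il22 (1.46) more, among the effector cytokines (2 and 2 of 20, or 11 less and 2 more adjusted over the list alone, adjusted p = 0.00016, but adjusted p = 0.42 with an estimated correlation). Interferon-stimulated genes responded less at 18 h in 3 of 30 (19 adjusted over the list alone, median -0.64, adjusted p = 3.3e-12, but adjusted p = 0.059 with an estimated correlation). Among eligible genes Ighv3-7 (3.16), Mst1r (2.45) and Ighg3 (1.96) had the largest positive terms, and Ccl1 (-2.71) and Trf (-2.65) the largest negative ones beside Ifng. limma called 410 genes at 6 h (111 more, 299 less) and 184 at 18 h (79 more, 105 less), and the split was 196 and 280 centred or 22 and 217 on TPM at 6 h, and 98 and 72 or 18 and 50 at 18 h. Without 1 library the 6 h count was 80 or 71 (WT 0 h replicate 1 or 2), 118 or 86 (KO 0 h), 163 (WT 6 h replicate 2) or 2305 (KO 6 h replicate 1). The 18 h count was then 7 or 16 (WT 0 h replicate 1 or 2), 24 or 8 (KO 0 h), 33 or 12 (WT 18 h) and 30 or 35 (KO 18 h). With a variance weight per group the counts were 144 and 2033, with a replicate block 202 and 51, and without the 6 h libraries 1635 at 18 h. Of the genes named at 6 h, Il17a kept its call only without KO 6 h replicate 1, and Nr4a1 and Khdrbs3 lost theirs without any 0 h library, Ackr1 also without WT 6 h replicate 2, and Lag3 without WT 0 h replicate 2 (limma adjusted p = 0.0510 to 0.143). Ifng passed without KO 6 h replicate 1 or 2 (down to 0.0260) and Il4 without replicate 2 (0.0186). At 18 h Ifng, Cd40lg, Il17f, Il22, Mst1r, Ighg3 and Ccl1 passed limma in none of the 8 fits with 1 library left out (adjusted p = 0.0505 to 0.203).

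In unstimulated KO BMDC several interferon-stimulated and maturation genes were lower and several glycolysis genes higher. Of 30 interferon-stimulated genes 18 fell and none rose (29 adjusted over the list alone, median -1.18, camera adjusted p = 2.7e-14, but adjusted p = 0.46 with an estimated correlation). Ifit2 fell from 28.6 ± 2.67 to 7.02 ± 2.32 FPKM (mean ± SD, n = 2, log2 fold change -1.91) and Usp18, which damps interferon receptor signalling, from 53.4 ± 6.94 to 16 ± 7.33 (-1.74). Of 19 dendritic maturation genes 9 fell (13 fell and 1 rose adjusted over the list alone, median -0.95, adjusted p = 2.1e-06, but adjusted p = 0.46 with an estimated correlation). The migration receptor gene Ccr7 went from 245 ± 36.9 to 54.8 ± 34.8 (-2.29) and Cd83 from 40.3 ± 7.1 to 11 ± 1.54 (-1.78). NF-kB feedback genes fell in 6 of 17 (11 adjusted over the list alone, median -0.47, adjusted p = 2.7e-05, but adjusted p = 0.069 with an estimated correlation), Traf1 from 28.2 ± 0.321 to 7.57 ± 2.66 (-1.80). Glycolysis genes rose in 8 of 16 (12 up and 1 down adjusted over the list alone, median 0.95, adjusted p = 1.9e-11, but adjusted p = 0.42 with an estimated correlation), Gpi1 from 431 ± 14 to 1140 ± 381 (1.36) and Pgk1 from 202 ± 8.15 to 456 ± 70.6 (1.16). Neutrophil and stroma markers fell in 3 of 11 and 5 of 7 (6 and 6 adjusted over the list alone, adjusted p = 6.1e-05 and 9.1e-05, but adjusted p = 0.46 and 0.46 with an estimated correlation). Mpo went from 4.05 ± 0.864 to 0.101 ± 0.081 (-2.19) and the matrix gene Sparc from 37.2 ± 16.8 to 6.71 ± 3.44 (-2.31). Cholesterol synthesis, MHC class II and TLR pathway genes fell in 2 of 20, 3 of 9 and 3 of 23 (6, 3 and 6 adjusted over the list alone, adjusted p = 0.0044, 0.0071 and 0.033, but adjusted p = 0.60, 0.46 and 0.46 with an estimated correlation). The alternative-activation markers diverged without a list call (2 up, 3 down of 12), Arg1 rising from 109 ± 46.3 to 1132 ± 611 (3.31) and Retnla falling from 358 ± 11.9 to 58.1 ± 8.73 (-2.61). Il12b, a subunit of IL-12 and IL-23, fell from 8.01 ± 2.44 to 1.19 ± 0.667 (-2.05), and Cxcl10 fell too (-1.67).

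Single genes with the largest changes among those eligible for naming in unstimulated BMDC included the imprinted gene Snrpn (3.83, 0.174 ± 0.038 to 15.8 ± 3.2 FPKM, mean ± SD, n = 2), Gsta1 (2.69) and Acpp (2.53) among the rises beside Arg1. The falls were led by Crxos (-4.77, 27.2 ± 2.18 to 0.034 ± 0.048), the kallikrein genes Klk1b1 (-4.72) and Klk1b11 (-4.66) and Htatip2 (-4.32, 41.5 ± 3.04 to 1.15 ± 0.457). The kallikrein and Gsta genes belong to multigene families, so their single values are uncertain. No gene of the proliferation, chromatin modifier, macrophage, myeloid, mast cell, T cell or sex-linked lists passed, and Klf9 (0.58) alone of the KLF and SP family did. The B cell and erythroid lists had a single tested member each in BMDC and were not tested as lists, and Ighm (-1.18) fell. Without stimulus limma called 1015 of 14987 genes, 462 higher and 553 lower, or 583 and 368 after median centring. The count was 225 without WT replicate 1, 194 without WT replicate 2, 165 without KO replicate 1 and 263 with these libraries fitted alone. Calls of Ifit2, Usp18, Ccr7, Gpi1, Sparc, Arg1, Cxcl10 and Klf9 held only when the library left out was KO replicate 2 (limma adjusted p otherwise 0.0518 to 0.243), and that of Ighm in no case (up to 0.190). The call of Cd83 ended without KO replicate 1 (0.0518) and that of Klk1b11 without WT replicate 2 (0.0643).

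With LPS the KO BMDC had several lower cytokine genes. Of 18 proinflammatory cytokines 8 fell and none rose (12 adjusted over the list alone, median -0.70, camera adjusted p = 1.7e-06, but adjusted p = 0.34 with an estimated correlation). Il12b fell from 532 ± 146 to 191 ± 15.4 FPKM (mean ± SD, n = 2, log2 fold change -1.45), Il6 from 282 ± 10.2 to 127 ± 42.4 (-1.18) and the pyrogen gene Il1b from 2477 ± 15.5 to 1519 ± 15.1 (-0.70). Tnf (486 ± 61.3 in WT, 427 ± 85.6 in KO, limma adjusted p = 0.66) and Il10 (adjusted p = 0.18) did not pass. NF-kB feedback genes fell in 5 of 17 (11 adjusted over the list alone, median -0.43, adjusted p = 1.7e-06, and adjusted p = 0.036 with an estimated correlation), Traf1 from 138 ± 15.8 to 64.2 ± 6.29 (-1.09). Dendritic maturation genes fell in 5 of 19 (8 adjusted over the list alone, median -0.68, adjusted p = 0.00011, but adjusted p = 0.47 with an estimated correlation), Cd83 from 89.2 ± 20.6 to 24.4 ± 5.97 (-1.83). Glycolysis genes rose in 9 of 16 (12 adjusted over the list alone, median 0.95, adjusted p = 5.8e-10, but adjusted p = 0.34 with an estimated correlation), Pkm from 560 ± 105 to 1181 ± 3.23 (1.09). Cholesterol synthesis genes fell in 3 of 20 (7 adjusted over the list alone, adjusted p = 5.6e-06, but adjusted p = 0.47 with an estimated correlation), Idi1 from 29.1 ± 4.15 to 7.75 ± 2.06 (-1.80). Neutrophil and stroma markers fell in 5 of 11 and 3 of 7 (8 and 5 adjusted over the list alone, adjusted p = 2.1e-05 and 0.00028, but adjusted p = 0.45 and 0.47 with an estimated correlation), among them Ngp from 145 ± 116 to 7.5 ± 4.57 (-3.94). No interferon-stimulated gene of 30 passed (0 adjusted over the list alone, median 0.08), although the list did (adjusted p = 0.043, but adjusted p = 0.71 with an estimated correlation). Among eligible genes Arg1 (3.56), Snrpn (3.37) and Gsta1 (2.92) rose most, and Htatip2 (-4.35) and Klk1b11 (-4.25) fell most beside Crxos, which stood at 34.3 ± 0.538 in WT and was listed at 0 in KO. With LPS limma called 947 genes, 444 higher and 503 lower. The count was 197 or 218 without WT replicate 1 or 2, 151 or 577 without KO replicate 1 or 2, and 549 with these libraries fitted alone. Calls of Il1b, Traf1 and Ngp ended without any 1 library (limma adjusted p = 0.0520 to 0.235), while those of Il12b and Pkm held only without WT replicate 1, Il6 only without KO replicate 1 and Arg1 only without WT replicate 2 (otherwise up to 0.168). Cd83 and Idi1 lost theirs without KO replicate 1 (0.0512 and 0.0546) and Klk1b11 without either WT library (up to 0.0648).

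With R848 several cholesterol synthesis, MHC class II and chemokine genes were lower in KO BMDC. Of 20 cholesterol synthesis genes 6 fell and none rose (20 adjusted over the list alone, median -0.74, limma camera adjusted p = 1.8e-10, but adjusted p = 0.52 with an estimated correlation), Idi1 from 31 ± 3.58 to 8.92 ± 1.77 FPKM (mean ± SD, n = 2, log2 fold change -1.70) and the sterol sensor partner Insig1 from 43.9 ± 2.4 to 19.7 ± 1.38 (-1.12). MHC class II genes fell in 3 of 9 (5 adjusted over the list alone, adjusted p = 0.0013, but adjusted p = 0.52 with an estimated correlation), the invariant chain gene Cd74 from 1895 ± 223 to 852 ± 132 (-1.16). Dendritic maturation genes fell in 4 of 19 (12 fell and 1 rose adjusted over the list alone, median -0.84, adjusted p = 4.8e-05, but adjusted p = 0.52 with an estimated correlation), among them the costimulator Cd80 from 25.5 ± 3.18 to 8.5 ± 2.08 (-1.49). Chemokines fell in 6 of 20 and rose in 1 (6 and 1 adjusted over the list alone, adjusted p = 0.035, but adjusted p = 0.59 with an estimated correlation). Cxcl10 went from 78.7 ± 23.1 to 30.2 ± 13.1 (-1.39), and the neutrophil attractant Cxcl5 rose from 32.5 ± 2.29 to 177 ± 3.46 (2.41). Glycolysis genes rose in 7 of 16 (13 adjusted over the list alone, adjusted p = 7.2e-08, but adjusted p = 0.52 with an estimated correlation). Neutrophil and stroma markers fell in 4 of 11 and 3 of 7 (8 and 5 adjusted over the list alone, adjusted p = 0.00016 and 0.0006, but adjusted p = 0.52 and 0.55 with an estimated correlation), Ltf from 56.3 ± 38.9 to 2.12 ± 1.06 (-4.05). Il18 fell (-1.94), while Il12b (321 ± 43.1 in WT, 160 ± 18.4 in KO, limma adjusted p = 0.054), Il6 (-0.76, adjusted p = 0.11) and Tnf (0.18) did not pass. Among eligible genes Egln3, an oxygen sensor (4.04), Snrpn (3.75) and Arg1 (3.43) rose most, and Crxos (-4.84), Klk1b11 (-4.58) and Htatip2 (-4.31) fell most. With R848 limma called 1056 genes, 540 higher and 516 lower. The count was 658 without WT replicate 1, 216 without KO replicate 1 and 649 without KO replicate 2, and it was 605 without the filter, 141 with these libraries alone and 396 with variance weights. The call of Egln3 ended without any 1 library (limma adjusted p = 0.0535 to 0.244), while those of Ltf and Arg1 held only without WT replicate 2 and Il18 only without KO replicate 2 (otherwise up to 0.190). Idi1, Cd80 and Cxcl10 lost theirs without KO replicate 1 (0.0526 to 0.0870), Cxcl10 also without WT replicate 1.

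**Figure D4:**
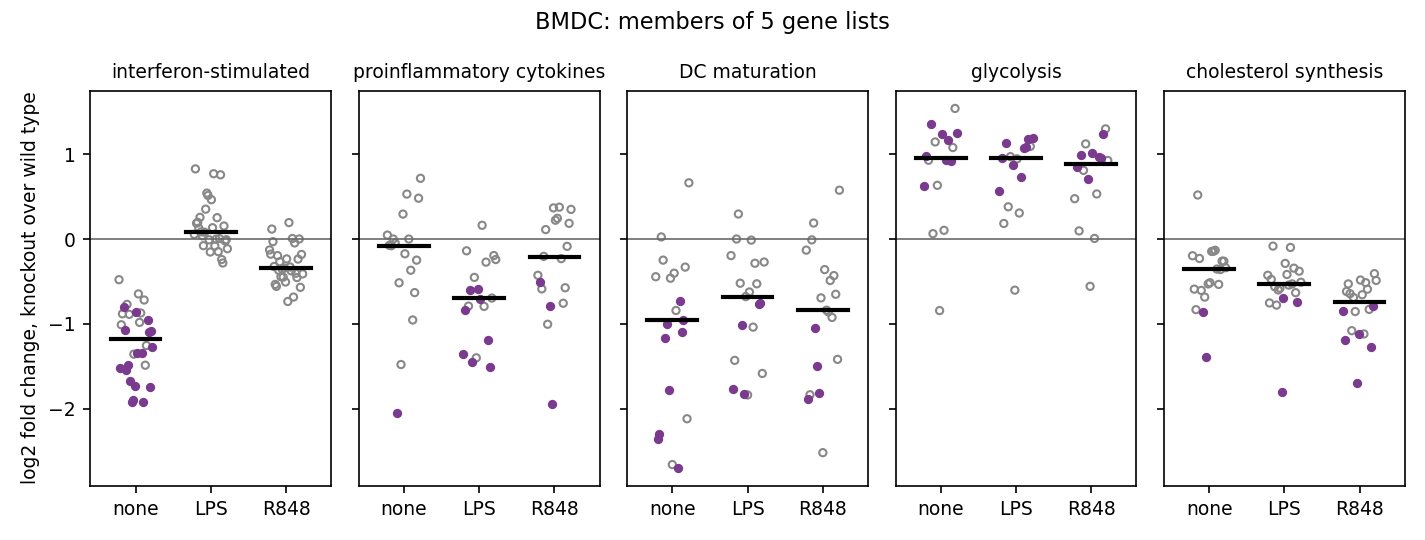
Log2 fold change (KO over WT, vertical axis) of the members of 5 gene lists in BMDC without stimulus, with LPS and with R848, 1 point per gene, filled where limma called the gene, with a bar at the median. The median of the glycolysis list was 0.95, 0.95 and 0.88.

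Averaged over the 3 conditions, limma called 3856 genes in BMDC by genotype, 1328 higher and 2528 lower in KO, or 1784 and 1827 after median centring, and 2305 with culture as a random block. Cholesterol synthesis genes fell in 17 of 20 (19 adjusted over the list alone, median -0.58, camera adjusted p = 4.5e-07, but adjusted p = 0.46 with an estimated correlation). Glycolysis genes rose in 13 of 16 and fell in 1 (13 and 1 adjusted over the list alone, median 0.96, adjusted p = 1.3e-10, but adjusted p = 0.46 with an estimated correlation). The glucose carrier gene Slc2a1 (1.31) and the lactate carrier gene Slc16a3 (1.16) were among them. Dendritic maturation genes fell in 15 of 19, with Fscn1 (-2.33) and Ccr7 (-1.85), and NF-kB feedback genes in 12 of 17 (16 and 13 adjusted over the list alone, adjusted p = 1.1e-05 and 0.00034, but adjusted p = 0.46 and 0.14 with an estimated correlation). Interferon-stimulated genes fell in 13 of 30 and proinflammatory cytokines in 7 of 18 (17 and 7 adjusted over the list alone, adjusted p = 0.00034 and 0.016, but adjusted p = 0.61 and 0.46 with an estimated correlation). Il18 (-1.60), Il12b (-1.50) and Il6 (-0.96) were among the latter.

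Stimulation of WT BMDC raised inflammatory genes strongly. With LPS interferon-stimulated genes rose in all 30 (30 adjusted over the list alone, median 2.64, camera adjusted p = 1.7e-25, but adjusted p = 0.15 with an estimated correlation). Proinflammatory cytokines rose in 17 of 18 and NF-kB feedback genes in all 17 (17 and 17 adjusted over the list alone, medians 2.28 and 1.99, adjusted p = 1.1e-19 and 1.5e-19, and adjusted p = 0.032 and 0.0016 with an estimated correlation). Among eligible genes Il6 (log2 fold change 7.02), Cxcl2 (6.65) and Cxcl1 (6.26) rose most, and the cannabinoid receptor gene Cnr2 (-3.26) and Lpar5 (-3.23) fell most. With R848 NF-kB feedback genes rose in all 17 and proinflammatory cytokines in 15 of 18 (adjusted p = 3.5e-19 and 1.0e-18, and adjusted p = 0.0015 and 0.037 with an estimated correlation). Interferon-stimulated genes rose in 23 of 30 (median 1.49, adjusted p = 2.4e-17, but adjusted p = 0.24 with an estimated correlation). Among eligible genes Cxcl2 (7.66), Cxcl1 (7.35) and Saa3 (7.02) rose most, and Lpar5 (-3.07) and Cnr2 were among those that fell most. Klf13 fell with both ligands (-0.71 and -0.71, limma adjusted p = 0.013 and 0.018), calls that ended without WT unstimulated or LPS replicate 1 (up to 0.0734) and without any 1 library for R848 (up to 0.101). Across both ligands limma called 7016 genes with LPS (1984 up, 5032 down) and 4535 with R848 (1525 up, 3010 down), around all-gene medians of -0.27 and -0.12. Relative to these medians, by centring, the splits were 3119 up and 2522 down with LPS and 2371 and 2077 with R848. The LPS count was 4670 without WT unstimulated replicate 1 and 4582 without WT LPS replicate 2, and the R848 count 2815 and 2783 without WT unstimulated replicate 1 and 2.

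Responses of the genotypes in BMDC were hard to tell apart. In the limma interaction test no gene passed for LPS, although 1004 had an unadjusted p under 0.05 and simulated terms of log2 size 1 were found in 31.3%. For R848 2 genes passed, Cxcl5 responding more in KO (3.46) and the RNase gene Rnase6 less (-1.88), with 1022 unadjusted. Without 1 library the R848 count was 0 (KO unstimulated replicate 1, WT R848 replicate 2 or KO R848 replicate 2) to 16 (WT R848 replicate 1), and the LPS count was at most 2 (without KO unstimulated replicate 1, or without KO LPS replicate 1). Without the filter the counts were 17 for LPS and 26 for R848. The interferon-stimulated list had positive medians without a called member, with LPS (0 of 30 called, 24 adjusted over the list alone, median 1.33, camera adjusted p = 2.8e-29, but adjusted p = 0.44 with an estimated correlation) and with R848 (0 and 0, median 0.88, adjusted p = 1.1e-13, but adjusted p = 0.79 with an estimated correlation). Proinflammatory cytokines had a negative median for LPS, again without a called member (0 of 18 called, 3 adjusted over the list alone, median -0.54, adjusted p = 1.1e-06, but adjusted p = 0.44 with an estimated correlation). The call of Rnase6 held only without WT R848 replicate 1, and that of Cxcl5 ended without any KO library or WT R848 replicate 2 (limma adjusted p up to 0.184 and 0.131).

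BMDM had 1 library per group, so KO and WT were compared across the 4 conditions as pairs in an additive fit. Interferon-stimulated genes were higher in KO in 19 of 30 (26 adjusted over the list alone, median 0.49, camera adjusted p = 9.8e-17, but adjusted p = 0.21 with an estimated correlation), with the antiviral genes Mx1 (log2 fold change 1.15) and Oas2 (0.77). Neutrophil genes rose in all 9 (9 adjusted over the list alone, median 1.97, adjusted p = 1.7e-15, but adjusted p = 0.17 with an estimated correlation). Ngp (2.62) and S100a9 (2.31) were among them. MHC class II genes rose in 6 of 8 and proinflammatory cytokines in 8 of 19 (6 and 8 adjusted over the list alone, adjusted p = 3.2e-08 and 9.4e-06, but adjusted p = 0.21 and 0.21 with an estimated correlation). They included H2-Aa (1.05), Cd74 (0.98), Il6 (1.23) and the anti-inflammatory cytokine Il10 (0.80). NF-kB feedback genes rose in 5 of 17, dendritic maturation genes rose in 6 of 18 and fell in 1, and chemokines rose in 3 of 19 and fell in 1 (adjusted p = 3.1e-06, 1.1e-05 and 0.0035, but adjusted p = 0.17, 0.17 and 0.21 with an estimated correlation). Cholesterol synthesis genes fell in 13 of 20 and proliferation genes in 17 of 24 (16 and 21 adjusted over the list alone, medians -0.46 and -0.38, adjusted p = 6.6e-06 and 9.4e-06, but adjusted p = 0.21 and 0.21 with an estimated correlation). Sqle (-0.92), Fdps (-0.90) and Birc5 (-0.66) were among them. Stroma markers fell in 6 of 8 and rose in 2 (adjusted p = 0.030, but adjusted p = 0.28 with an estimated correlation), and glycolysis genes fell in 5 of 16 without a list call (adjusted p = 0.22). Tnf (-0.20, limma adjusted p = 0.13) and Il12b (-0.43, adjusted p = 0.14) did not pass, and Klf13 fell (-1.43, adjusted p = 0.0068). Among genes eligible for naming, so without small RNA genes and predicted models, Apol7c (3.16), Prg2 (2.91) and Gdf3 (2.46) rose most beside Ngp, and Htatip2 (-3.96), Rspo2 (-2.19) and Actg2 (-1.91) fell most. Over the 4 pairs limma called 3273 of 15385 genes, 889 higher and 2384 lower around an all-gene median of -0.11. The count was 2055 (1248 higher, 807 lower) after median centring, 2530 (968 higher, 1562 lower) on TPM, 677 without the filter, and 1498, 1567 and 690 without the LPS, R848 or ODN1826 pair.

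Single BMDM pairs, which carry no p-value, showed the neutrophil and interferon differences in each condition. Among genes at 5 FPKM or more, 133 were higher and 108 lower by 2-fold in unstimulated KO, 195 and 176 with LPS, 161 and 196 with R848, and 180 and 146 with ODN1826. Neutrophil genes were higher by 2-fold in 10 of 10, 8 of 9, 8 of 8 and 8 of 8, with medians of 2.05, 1.70, 1.76 and 2.17. Interferon-stimulated medians were 0.411, 0.242, 0.513 and 0.736, each at percentile 100 of 10000 random lists of matched level, and cholesterol medians were -0.382, -0.455 and -0.655 in the first 3 conditions. In R848 the KO and WT libraries listed Il6 at 113.9 and 28.5 FPKM and Il10 at 9.38 and 4.78, and with ODN1826 at 77.8 and 29.2 (Il6) and 12.1 and 3.81 (Il10). Il12b went the other way, 40.1 against 80.2 with LPS and 659.9 against 1016 with ODN1826. In the WT pairs interferon-stimulated genes were higher by a median of 3.38 with LPS, 2.61 with R848 and 2.05 with ODN1826. In the KO pairs the medians were 3.32, 2.54 and 2.30.

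Sle3k and B6 T cells differed little in effector cytokines in single pairs, none of which differed by 2-fold at 6 h (0 of 20) or 18 h (0 of 22). At 6 h effector cytokines had a median log2 ratio of 0.35 and proinflammatory cytokines 0.338. Both stood at percentile 100 of matched random lists, as did chemokine and proliferation genes, and quiescence genes (-0.169) at 0. Sle3k and B6 libraries listed Ifng at 165.8 and 87.5 RPKM, Il2 at 73.6 and 51.8, Il17a at 15.6 and 9.14 and Il10 at 15.9 and 8.20. Medians of marker lists were 0.894 for neutrophil, 0.714 for erythroid, 0.45 for B cell, 0.345 for myeloid and 0.342 for NK genes, and MHC class II genes had 0.344. At 18 h effector cytokines had a median of 0.267 (percentile 100), with Ifng at 363.6 and 254 and the follicular helper cytokine Il21 at 29.4 and 19.0, and the hemoglobin genes Hba-a2 (250.6 and 47.9) and Hbb-b1 (313.4 and 67.0) also differed. Medians at 18 h were 0.844 for neutrophil, 0.666 for erythroid, 0.518 for B cell and 0.398 for myeloid genes, above that of the cytokines, and quiescence genes had turned to 0.153 (percentile 100). In unstimulated BMDC proliferation genes had a median of -0.769 and with R848 -0.621 (percentile 0 both times), while interferon-stimulated genes had 0.234 with R848 (percentile 100). Mast cell markers had -0.637 and -0.94 in the same order (2 and 3 of 6 lower by 2-fold), and T cell, NK and neutrophil markers -0.488, -0.476 and -0.359 without stimulus. Neutrophil genes had -1.12 with R848, S100a9 standing at 2.84 in Sle3k and 17.0 in B6. Tnf stood at 405.3 and 256.1 with R848 and Il6 at 91.6 and 84.3. The BMDC strains also differed in sex, since the X-inactivation transcript Xist stood at 0.001 in Sle3k and 29.9 in B6 and the Y-linked Ddx3y at 12.1 and 0, so strain and sex cannot be separated there. By 2-fold, 78 genes were higher and 31 lower in T cells at 6 h, 49 and 22 at 18 h, 6 and 15 in unstimulated BMDC and 9 and 9 with R848. In the additive limma fit over the 4 pairs 2 of 11507 genes passed, Dynlt1b (1.08) and the X-linked Haus7 (1.04), with 425 unadjusted, and the count was 0 without the filter, 4 without the T 6 h pair, 8 without the unstimulated BMDC pair and 4 without the R848 pair. Camera called 20 of 29 lists there at the preset correlation and 0 with an estimated one.

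Sub-congenic T cells at 0 h differed in B cell genes and in Htatip2. Line 157-233 against line 157-27 had 108 genes higher and 90 lower by 2-fold. B cell markers were higher by 2-fold in 6 of 10 (median 1.26, percentile 100 of matched random lists), quiescence, KLF and SP family and chromatin modifier genes had medians of 0.346, 0.279 and 0.264, and neutrophil genes -0.823 (percentile 0). Klf13 stood at 56.6 RPKM in 157-233 and 39.9 in 157-27. Htatip2 was at 1.57 and 20.3, the ferritin gene Ftl2 at 81.0 and 0.797, and the immunoglobulin gene Igkv5-48 at 43.0 and 396.

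Directions of the Sle3k and KO effects were compared across genes, which are not independent replicates, and in T cells across sexes by Xist. Among genes called by genotype, 496 of 1330 had the same direction in T cells at 6 h (37.3%, 34.7 to 40%), 185 of 430 at 18 h (43.0%, 38.3 to 47.9), 276 of 597 in unstimulated BMDC (46.2%, 42.2 to 50.3) and 397 of 622 with R848 (63.8%, 59.9 to 67.6). Over all tested genes the shares were 46.1%, 54.5%, 51.9% and 55.2%. Ifng, lower in KO T cells at 6 h and 18 h, stood higher in the single Sle3k than B6 library both times.

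Genes near Klf13 were called more often than others in T cells and BMDC. Within 20 Mb of Klf13 lay 88 of 3459 called genes in T cells on average (2.54%, against 1.45% of the 17059 tested, Fisher odds ratio 2.193, p = 2.5e-08) and 77 of 3856 in BMDC (2.0% against 1.48%, p = 0.0032). In BMDM it was 55 of 3272 (1.68% against 1.44%, Fisher p = 0.215). Within 40 Mb the BMDC excess no longer passed (Fisher p = 0.139). Among called genes with a change of at least 2-fold, 20 of 285 in T cells lay within 20 Mb (7.02%, Fisher odds ratio 5.477), 18 of 385 in BMDC (4.68%, odds ratio 3.461) and 8 of 213 in BMDM (3.76%, Fisher p = 0.0123), and within 40 Mb 26 of 385 in BMDC (6.75%, Fisher p = 0.0037). Htatip2 (ENSMUSG00000039745.8, chromosome 7, 49759115 to 49773975) lay in this region and fell in all 3 cell types. Its values were 13.82 to 43.6 FPKM in WT libraries and 0 to 1.47 in KO libraries. The share of called genes on other chromosomes was 91.8% in T cells, 92.7% in BMDC and 92.4% in BMDM.

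**Figure D5:**
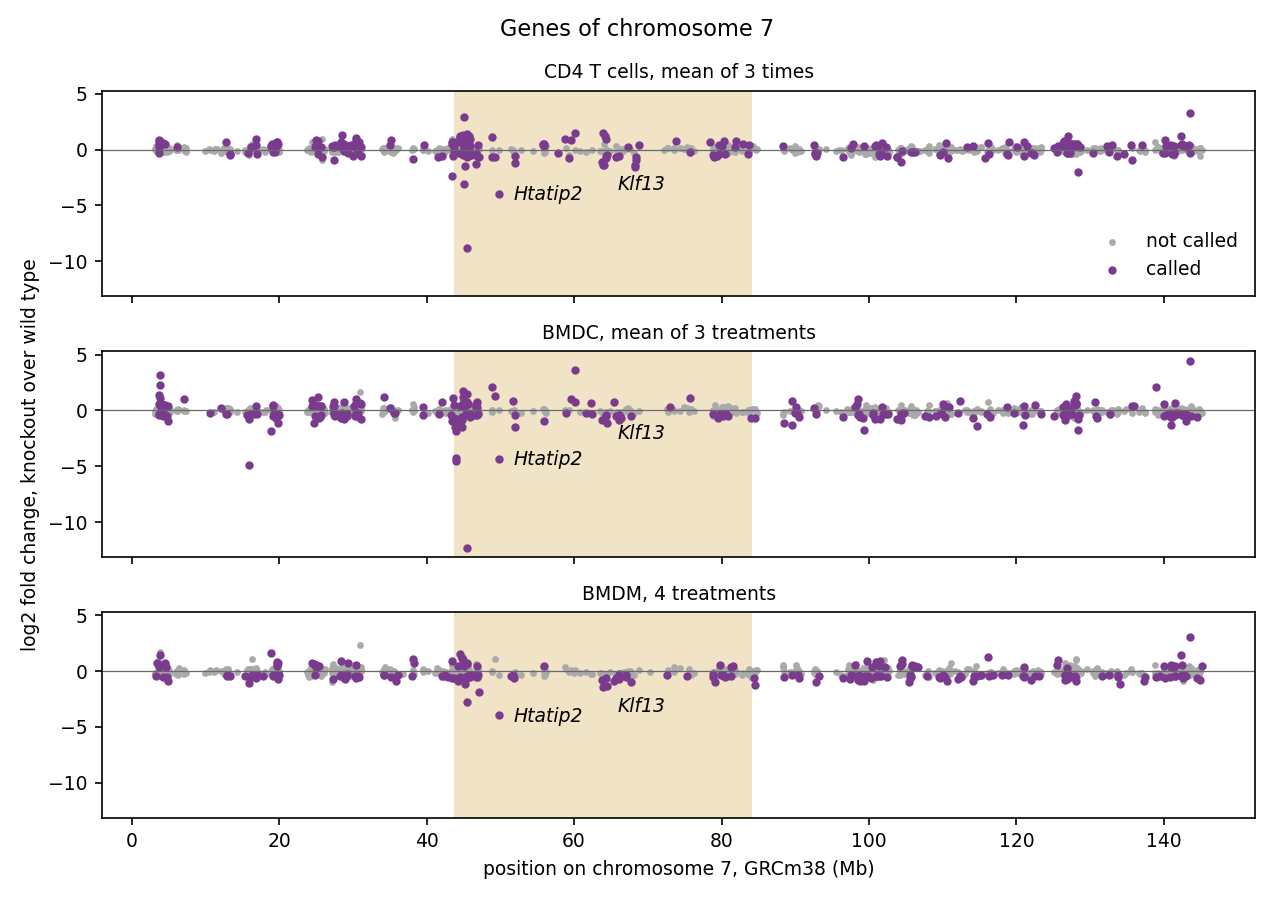
Log2 fold change (KO over WT, vertical axis) along chromosome 7 (Mb, horizontal axis) in T cells and BMDC, as the average of 3 conditions, and in BMDM, 1 point per tested gene, with the region within 20 Mb of Klf13 shaded. Klf13 and Htatip2 are labelled, and the lowest point in T cells and BMDC was Gm22133.

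Few genes changed alike in all 3 cell types. Of 13153 genes tested in each, 71 were called higher (4.9 expected of independent lists) and 87 lower (27.0) everywhere. BMDC and BMDM shared 315 lower (314.3 expected) and 118 higher (51.7), and T cells shared more than expected with each. Similar genes are counted apart, and most of the largest shared changes were in small RNA genes, predicted models and pseudogenes. They included Htatip2 (-4.00, -4.33 and -3.96 in T cells, BMDC and BMDM). Others, picked after the values were seen, were Ppbp (1.21, 1.32 and 1.47), Pf4 (1.34, 0.78 and 1.81), X-linked Mid1 (1.16, 0.99 and 1.71) and Prkar2a (-0.98, -0.82 and -0.92). Across genes, which are not independent replicates, the KO effect correlated between T cells and BMDC (Pearson r 0.305, Spearman rho 0.166) and T cells and BMDM (0.322 and 0.2), and less between BMDC and BMDM (0.121 and 0.002).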

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

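How the cell mixture, the interferon genes and shared direction near Klf13 were weighed was chosen only after results were seen, as were splits that keep pairs or cultures. The camera tests, fits without 1 library, other splits and shares of genes off chromosome 7 were planned. The KO effect differed between times of T cell activation for 410 genes at 6 h and for 184 genes at 18 h, and in BMDC with R848 for 2 genes. The interferon-stimulated list had a median interaction of -1.254 at 6 h in T cells. The counts in T cells fall to 71 and 7 when 1 WT library of 0 h is left out, and rise to 2305 at 6 h without KO 6 h replicate 1 and at 18 h to 2033 with a variance weight per group and 1635 without the 6 h libraries.

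Interferon-stimulated genes, lower in KO T cells at 6 h, were weighed first. Their rise at 0 h (17 of 30) lost its list call with an estimated correlation (adjusted p = 0.063). TPM and median centring, which only rescale libraries, kept the 6 h median at -0.7802 or lower, and other faults of normalization stay open. Spread among the 6 h libraries would bring this median towards 0 without 1 of the 4, but the highest median was then -0.7663. Weaker KO activation may contribute but was not tested separately. Early TCR genes had a median interaction of -0.68 at 6 h (8 of 22 passed). An estimated correlation ended this list call (adjusted p = 0.39) and that of their WT rise, so decides nothing. Non-T cells, whose markers differed between genotypes at 0 h, also stay open.

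Proliferation genes were lower in KO T cells at 0 h, where naive cells are not dividing. A lower T cell share alone in KO would raise other markers alike. T cell markers rose, and erythroid and neutrophil medians were -1.015 and 2.35. Erythroid precursors in WT, which would dilute T cell RNA, stay open. By 18 h in WT the erythroid list fell by a median of 2.46, with proliferation at -1.97. Macrophage gene C1qa fell too, singling out no cell type. The hemoglobin gene Hba-a1, which has close paralogs, stood at 4661 FPKM in WT and 2217 in KO at 0 h after magnetic bead selection. Other dividing cells stay open.

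Genes called by genotype were weighed against DNA of another strain around the targeted locus. Of the genes called on average, 91.8% in T cells and 92.7% in BMDC lay on chromosomes other than 7. Of all tested genes 7.27% and 7.45% lay on chromosome 7, so any genome-wide source gives such shares. Misassigned reads of linked genes and strain DNA on other chromosomes were not tested. A linked gene such as Htatip2 could change genes elsewhere, which no test here separates from an effect of KLF13. Linked DNA thus cannot be told apart for these calls. For the genes within 20 Mb of Klf13 it also cannot be told apart from an effect of KLF13: of those called in T cells on average and tested in all 3 cell types, 53.3% changed in the same direction in all 3, against 43.0% elsewhere (Fisher p = 0.115). A difference in age, litter or housing between the genotypes stays open and was not tested.

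Whether a chance arrangement of the libraries gives as many genes was checked with other splits. In T cells 1 of 100 splits, the real one, gave as many genes (3460). The highest other (2778) nearly repeats it, with 5 of the 6 WT libraries in its first arm. Chance is excluded only if the libraries are independent. In BMDC 1 of 100 splits, the real one, gave as many (3856, highest other 143), but libraries of a genotype with the same replicate number were alike across conditions (consensus correlation 0.2639), and most splits break such cultures apart. The splits that keep them whole number 3, too few for a share under 0.05 (real 3856, highest other 8). In BMDM 1 of 32 splits gave as many (3273, highest other 3), but all others that are not within pairs put both libraries of some conditions in 1 arm, and the 8 splits within pairs are too few for a share under 0.05 (real 3273, highest other 1). For Sle3k against B6, 5 of 32 splits gave 2 genes or more and the highest gave 84, which points to a structure of the libraries other than strain, and the 8 splits within pairs are again too few (real 2, highest other 0). Both genes called by strain lay on other chromosomes than Klf13, and with 2 genes the share within 20 Mb has an upper bound of 84.2%, so whether the congenic interval is the source cannot be told apart.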

How the results depend on the processing

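Alternatives with TPM, a variance weight per group, culture as a random block, a crossed block, no 6 h libraries, median centring in the list tests and the orders of columns in fry were chosen only after the data were seen, and the rest were planned. The cause of a moved count was not tested unless stated.

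Leaving out 1 library, where the lone sample is assumed to vary like the other groups, gave 641 to 899 genes in T cells at 0 h, 1066 to 3230 at 6 h, 339 to 397 at 18 h, 2307 to 4339 on average, 71 to 2305 for the interaction at 6 h and 7 to 35 at 18 h. The counts of the WT responses were 5495 to 6929 at 6 h and 5090 to 5524 at 18 h. In BMDC the ranges were 165 to 874 without stimulus, 151 to 577 with LPS, 216 to 753 with R848, 2631 to 3952 on average, 4582 to 5000 and 2783 to 4598 for the WT responses to LPS and R848, and 1 to 2 and 0 to 16 for their interactions. Fewer samples lower most of these counts by construction. The BMDM count was 1498, 1567 and 690 without the LPS, R848 or ODN1826 pair, and the Sle3k count 4, 8 and 4 without the T 6 h, unstimulated BMDC or BMDC R848 pair.

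Fitting the compared groups alone gave 5741 genes in T cells at 0 h and 167 at 6 h, and in BMDC 263 without stimulus, 549 with LPS and 141 with R848. The 6 h replicates lay furthest apart (median difference 0.218 in WT and 0.267 in KO, against 0.060 and 0.072 at 0 h), so the pooled spread is too wide for 0 h and too narrow for 6 h. With a variance weight per group the T cell counts were 6912, 388 and 1416 at 0, 6 and 18 h, and 144 and 2033 for the interactions at 6 h and 18 h. The BMDC R848 count was then 396 and its interaction 0. Without the 6 h libraries the T cell counts were 5507 at 0 h, 1567 at 18 h, 5383 on average and 1635 for the interaction at 18 h.

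On TPM 1738 genes were called in T cells at 0 h, 239 and 68 in the interactions at 6 h and 18 h, and 0 in the BMDC R848 interaction. A pseudocount of 0.1 gave 88 in the interaction at 18 h. A replicate block gave 202 and 51 in the T cell interactions and 0 in the BMDC R848 interaction, although pairing of replicate numbers is not established. Culture as a random block gave 2305 genes in BMDC on average. Without the filter on low values the counts were 605 in BMDC with R848, 17 and 26 for the LPS and R848 interactions, 677 in BMDM and 0 for Sle3k. Median centring gave 2055 in BMDM.

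Among lists, the estimated correlation left 0 of 16 calls in T cells at 0 h, 2 of 8 at 6 h, 1 of 9 at 18 h, 0 of 12 on average, 4 of 14 and 1 of 17 in the WT responses at 6 h and 18 h, and 1 of 12 and 0 of 16 in the interactions. In BMDC it left 0 of 9 without stimulus, 1 of 9 with LPS, 0 of 8 with R848, 0 of 10 on average, 2 of 9 and 2 of 12 in the WT responses to LPS and R848, and 0 of 2 and 0 of 3 in the interactions. It left 0 of 17 in BMDM and 0 of 20 for Sle3k. fry, which tests a different question, called 26 lists in the WT response at 18 h, 9 in the interaction at 18 h, 16 in BMDC on average, 16 in the WT response to LPS, 0 and 1 in the BMDC interactions, 11 in BMDM and 0 for Sle3k. The fry result depends on the order of the condition columns in these small fits, and over all 24 orders it called 10 to 13 lists in BMDM and 0 for Sle3k.

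In single pairs a pseudocount of 5, a minimum of 1 and a minimum of 20 gave 125, 440 and 126 genes in unstimulated BMDM (main 241), 167, 647 and 183 with LPS (371), 172, 643 and 172 with R848 (357), and 162, 573 and 169 with ODN1826 (326). They gave 56, 169 and 48 in Sle3k T cells at 6 h (109), 25, 130 and 21 at 18 h (71), 6, 36 and 9 in unstimulated BMDC (21), and 10, 33 and 8 with R848 (18). For the sub-congenic lines the first gave 117 and the last 106 (main 198). A minimum moves these counts by construction. Over all tested genes, in place of called ones, 46.1% had the same direction in Sle3k and KO T cells at 6 h and 55.2% in BMDC with R848, and the shares turned to 54.5% in T cells at 18 h and 51.9% in unstimulated BMDC. The BMDC excess near Klf13 did not pass within 40 Mb (Fisher p = 0.139), except at 2-fold or more (0.0037).

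Of 221 called gene results among the 237 in the text, none reversed under any alternative. Of 3205 alternative values 2773 stayed on the same side of the threshold, 421 lost a call and 11 gained one, 269 of the losses with 1 library left out. limma without trend left all 237 on the same side.

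Simulated changes of 0.5 in log2 were found in 6.0% of genes in T cells at 0 h and 18 h and in 4.5% in unstimulated BMDC, against 61.2% in BMDM and 95.5% in Sle3k, and changes of 1 in the first 3 in 70.1%, 73.1% and 79.1%. In the interactions changes of 1 were found in 29.9% and 44.8% in T cells and 31.3% and 38.8% in BMDC.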

Other observations

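All values here were picked after the data were seen, though the planned rule had named Klf13 and Htatip2. Htatip2 followed genotype in each of the 32 libraries of the KO set. The library labelled KO R848 replicate 1 in BMDC, in which Klf13 stood at 20.2 FPKM, listed Htatip2 at 0.63 FPKM, against 32.77 and 39.79 in the WT R848 libraries. Among the Sle3 set Htatip2 stood at 20.33 RPKM in line 157-27 and 1.57 in line 157-233, and at 11.29 and 11.58 in B6 and Sle3k T cells at 6 h.

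Line 157-27 has a sample title naming B6 and line 157-233 one naming NZW, and both are single libraries at 0 h without a matching B6 library.

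Xist stood at 0 to 0.08 FPKM in T cells and BMDC of the KO set, and 36.84 to 113.44 in BMDM of both genotypes. B6 and Sle3k T cells had 24.09 to 40.96 RPKM, so sex differed by cell type and, in T cells, by set.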
